A study of Mus musculus with 2 samples.

How the data were processed

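Total RNA-seq was measured in 2 libraries of neural tube tissue from B6NCrl mouse embryos at embryonic day 11.5, pools of 109 and 88 embryos that the labels name biological replicates 1 and 2 of 1 experiment. Per the labels' protocols, RNA was extracted with Ambion mirVana, the RNA kept was longer than 200 bases, each library started from 10 ng, spike-in RNAs were added and the general protocol was SmartSeq. The labels title the assay total RNA-seq, and which of these describes the libraries is not settled by the sources used here. Levels of RNAs without a poly(A) tail, such as most replication-dependent histone RNAs, Terc and Rn7sk, are to be read with that doubt. Whether the libraries keep strand information is not given in the sources used here, so reads of overlapping genes on opposite strands were treated as not separable.

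Expected counts, the estimated reads per gene and per transcript, were deposited by the authors together with TPM values, made on the mm10 build with GENCODE release M4, per the deposited file descriptions, which also list transcriptome alignments. The deposited TPM values sum to the same total in each library and include the spike-ins, which took 13.2% of TPM in replicate 1 and 11.8% in replicate 2. The share of each transcript in its gene was deposited by the authors as a percent. The effective lengths in the deposited files were 99 bases below the lengths, so entries close to that length reach a high TPM from few counts. The aligner and the quantifier, with their versions, are not given in the sources used here. A second, posterior mean estimate of each value in the same files was used only as an alternative.

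Gene symbols, types and coordinates came from GENCODE M21 on GRCm38, the build of mm10, joined on the gene identifier without its version; 42462 of 43346 identifiers (97.96%) matched and 884 did not, which were kept under their identifiers. The files also list 97 spike-ins and 26248 entries named by a number. Spike-ins and numbered entries were left out of gene counts and lists. Total expected counts were 27638068 in replicate 1 and 29166901 in replicate 2, and a median of 27 and 26 counts lay behind 1 TPM. Where a gene had 0 counts, the level that 3 counts would give was taken as the upper limit. These limits and the exact binomial test cover counting error only, and reads without molecular identifiers are not independent molecules. Bootstrap and Wilson intervals cover the sampling of genes, list members or spike-ins and not the variation between pools.

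Before the data were examined, 38 lists of marker and pathway genes (474 genes), the tests, the alternatives and the rule for naming genes were fixed. The rule named the 4 members of each list with the highest mean TPM and up to 2 members below 1 TPM in both libraries, the 15 highest genes outside the mitochondrial genome, the 10 largest ratios in each direction at a mean of 100 counts or more, and, of the isoform list, the 6 highest genes and the 3 largest moves of the leading transcript. Genes named by an intended comparison, such as Slc32a1, and Hist2h2aa2 and mt-Co3, which share the sequence of a named gene, stand outside it; these last were chosen after their values were seen, as was the count of nuclear copies of mitochondrial genes. Some genes that the rule names are not reported here. Lists share members, so their results are not independent.

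Expected counts were rounded to whole numbers, and edgeR 4.0.16 in R 4.3.3 gave TMM factors (0.996 and 1.004) and log2 ratios with a prior count of 2. It also gave the common dispersion from a design with an intercept only, over genes and spike-ins with 10 counts in both libraries. Spike-ins that passed the filters also entered the TMM factors. Ratios used genes with 10 counts in at least 1 library. DESeq2 1.42.0 was used for alternative size factors and dispersions. A two-sided exact binomial test per gene compared the rounded counts with the scaled library sizes, with Benjamini-Hochberg adjustment at 0.05; 1 library stood on each side, so it compares these libraries only. A list median was placed among 10000 random lists of the same size, drawn from protein-coding genes for levels and matched on mean expression in 20 bins for ratios. List differences used log2(TPM + 1) and 10000 random splits of both lists together. Windows of 100 bases of each transcript that occur in another gene gave the percent of shared sequence. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did the remaining steps.

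The steps were tested on simulated counts for the comparison of replicate 2 with replicate 1. With no changed genes, a simulated coefficient of variation of 0.1 was recovered as 0.1 over 16346 entries, spike-ins included. With 200 strongly changed genes the estimate rose to 0.144. All 100 genes changed 3-fold and all 100 changed 4-fold were found past 2-fold in the right direction, and none of 12109 unchanged genes at 100 counts was. Of 200 unchanged lists of 15 genes 4% fell outside the random range, and 99% of lists shifted by 0.3 were found. Simulated genes varied independently and these lists held genes of 100 counts or more, so lists of co-regulated or low-count genes were not covered. Shifts below 0.3 were not simulated, and most list medians reported outside the random range were smaller than that.

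Alternatives covered the pseudocount, the filters, TMM against DESeq2 or spike-in scaling, the posterior mean TPM, library-scaled counts in place of TPM, and each replicate alone. Rescaling TPM to the mouse genes, spike-in scaling of the lists, and leaving out genes with shared sequence were added after the data were seen. No test between conditions was possible with 1 group.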

Results

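RNA was sequenced from the neural tube, the embryonic precursor of the brain and spinal cord, of B6NCrl mouse embryos at embryonic day 11.5. The labels title the assay total RNA-seq. The series held 1 group of 2 biological replicates. Replicate 1 was made from tissue of 109 embryos and replicate 2 from tissue of 88 embryos, with both sexes pooled in each. Each library started from 10 ng of RNA longer than 200 bases, to which synthetic spike-in RNAs had been added. Replicate 1 held 27638068 expected counts and replicate 2 held 29166901, over 22064 and 22069 genes with at least 1 count. At this depth a gene at 1 TPM (a transcript share scaled to a common total) rested on a median of 27 expected counts in replicate 1 and 26 in replicate 2. No treatment, age or tissue was set against another, so the questions were which transcripts the tissue held and how closely the 2 pools matched. Levels are given as mean TPM ± SD over the 2 libraries (n = 2), and a gene was called detected at 1 TPM or more in both.

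Transcripts of dividing progenitors and of young neurons were both abundant. All 14 neural progenitor genes were detected, with a median of 47.5 TPM. The intermediate filament gene Vim stood at 971 ± 16.4 TPM and Fabp7, a fatty acid binding protein of radial glia, at 735 ± 13.2 TPM. Cdh2, which encodes N-cadherin, reached 166 ± 15.2 TPM, and the Notch effector Hes5 reached 161 ± 17.1 TPM. All 18 cell cycle genes were detected, with a median of 155 TPM, led by the mitotic kinase Cdk1 at 291 ± 1.79 TPM and its partner cyclin Ccnb1 at 270.3 ± 1.87 TPM. Top2a, the topoisomerase of dividing cells, stood at 265 ± 4.20 TPM and the replication clamp gene Pcna at 254 ± 7.82 TPM.

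The 16 postmitotic neuron genes were all detected as well, and their median was higher, at 176 TPM. Tubb3, the neuronal beta-tubulin gene (ENSMUSG00000062380.3, chromosome 8, 123411424 to 123422015, GRCm38), had 740.3 ± 86.8 TPM. The neurofilament gene Nefl had 354 ± 29.2 TPM, and the microtubule regulators Stmn2 and Stmn3 had 343 ± 29.1 and 322 ± 25.7 TPM. All 12 neurogenesis genes were detected at a median of 32.6 TPM, with Hes6, which promotes neuronal differentiation, at 235 ± 21.8 TPM and the antiproliferative gene Btg2 at 81.9 ± 8.0 TPM. The Notch ligand genes Dll3 and Dll1 followed at 58.4 ± 5.88 and 47.7 ± 4.21 TPM. The progenitor median lay below the neuron median by a log2 difference of -1.85 ± 0.14 (SD, n = 2), at percentile 1.49 of 10000 random splits of the same genes. The difference had the same sign in both libraries. It depends on the genes chosen for each list and does not measure the numbers of progenitors and neurons.

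Of 13 glial genes 7 were detected, at a median of 13.6 TPM. Among them were Sox9, which progenitors also express, at 127 ± 0.134 TPM and the gliogenic factor Nfia at 23.5 ± 1.17 TPM. The growth factor receptor gene Pdgfra, which also stands in the paraxial mesoderm and connective tissue list, had 30.99 ± 1.05 TPM. Olig1, an oligodendrocyte lineage factor, had 0.315 ± 0.0919 TPM, and Gfap, the astrocyte filament gene, had 0.120 ± 0.0424 TPM, from 4 and 7 expected counts.

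**Figure D1:**
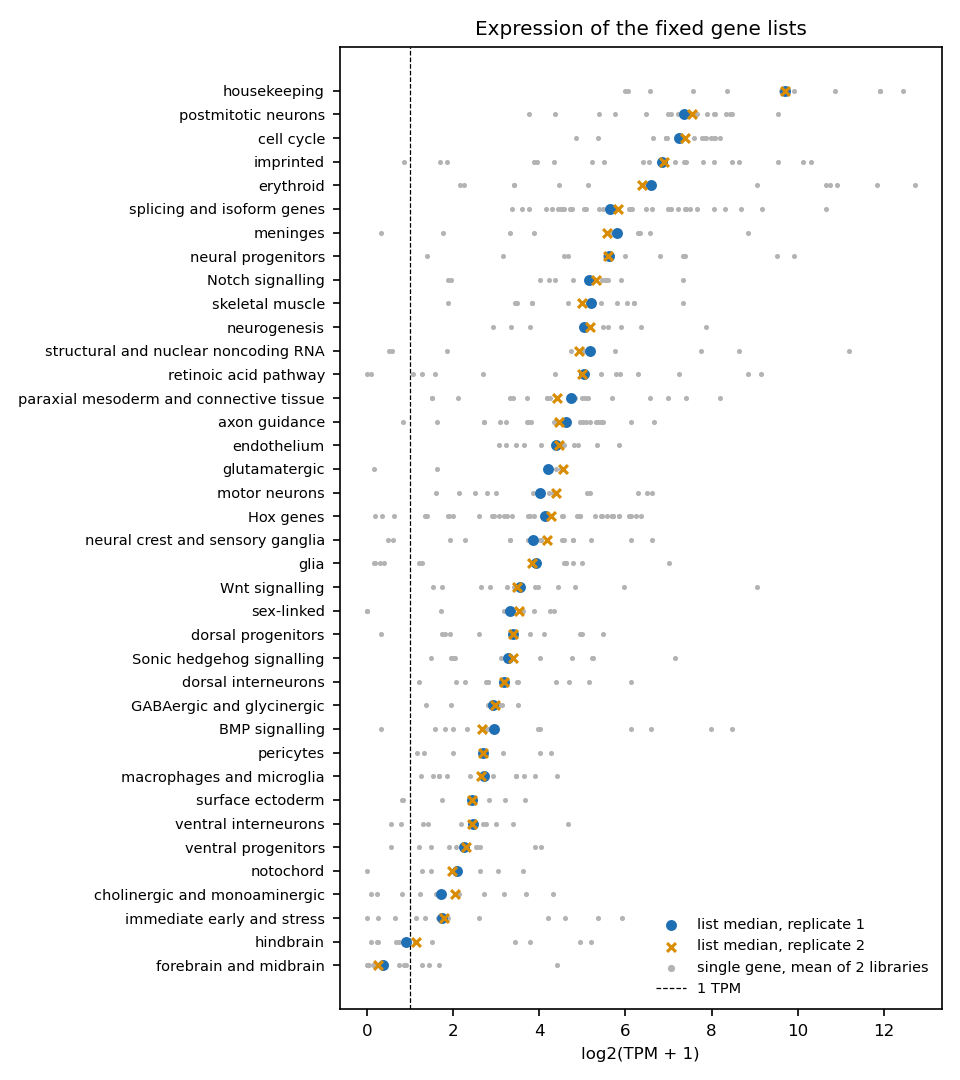
Expression of the 38 gene lists fixed before the data were examined, ordered by median. The horizontal axis is log2(TPM + 1); grey points are single genes (mean of the 2 libraries), filled circles and crosses are the list medians in replicates 1 and 2, and the dashed line marks 1 TPM. Housekeeping genes (median 831 TPM) and postmitotic neuron genes (176 TPM) stood at the top, and forebrain and midbrain genes (0.265 TPM) at the bottom.

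Genes of both dorsal and ventral progenitor domains of the neural tube were detected. Of the 12 dorsal genes 4 also stand in other lists, as do 4 of the 10 ventral genes. Levels in whole tissue do not assign these transcripts to the domains. Of 12 dorsal progenitor genes 11 were detected, at a median of 9.57 TPM, led by the roof plate and dorsal homeobox gene Msx1 at 43.9 ± 0.177 TPM. Pax3 and Olig3, transcription factors of dorsal progenitors, followed at 31.1 ± 4.08 and 29.9 ± 0.905 TPM, and Msx2 stood at 16.2 ± 0.205 TPM. Gdf7, a roof plate growth factor, was the exception at 0.260 ± 0.0566 TPM. Of 10 ventral progenitor genes 8 were detected, at a median of 3.99 TPM. Prdm12, which also stands in the neural crest and sensory ganglion list, had 15.5 ± 3.90 TPM and Dbx1, the homeobox gene of intermediate progenitors, had 14.1 ± 0.912 TPM. The ventral homeobox genes Nkx6-2 and Nkx6-1 had 5.17 ± 0.622 and 4.90 ± 0.389 TPM, while Nkx2-9 had 0.485 ± 0.262 TPM. The dorsal median exceeded the ventral median by a log2 difference of 1.1 ± 0.03 (SD, n = 2). That difference lay at percentile 92.0 of 10000 random splits of the same genes, inside their central 95%.

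All 14 dorsal interneuron genes were detected, at a median of 8.10 TPM, and 5 of them also stand in other lists. Levels in whole tissue do not assign these transcripts to neurons born dorsally. The most abundant was Pou4f1 (ENSMUSG00000048349.9, chromosome 14, 104461676 to 104467999), a POU-domain factor of sensory and dorsal neurons, at 68.8 ± 10.4 TPM. The LIM homeobox genes Lhx1 and Lhx5 had 34.9 ± 2.60 and 24.7 ± 0.431 TPM, and Tlx3, a selector of excitatory dorsal neurons, had 20.0 ± 3.63 TPM. Of 12 ventral interneuron genes 10 were detected, at a median of 4.45 TPM, with Foxp2 at 24.5 ± 0.0990 TPM, Lhx4 at 9.49 ± 1.92 TPM and Gata3 at 6.95 ± 0.141 TPM. Vsx1 and Evx2 stayed below 1 TPM, at 0.740 ± 0.0566 and 0.480 ± 0.0849 TPM. The dorsal minus ventral interneuron difference was 0.74 ± 0.02 on the log2 scale (SD, n = 2), at percentile 97.1 of random splits and still inside their central 95% of -0.74 to 0.74.

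Motor neuron genes were all detected, 13 of 13, at a median of 17.7 TPM. Isl1, the LIM homeobox gene required for motor neurons and also expressed in sensory neurons (ENSMUSG00000042258.9, chromosome 13, 116298281 to 116309689), had 97.7 ± 16.5 TPM. Foxp1, which marks limb motor neurons, had 89.3 ± 3.38 TPM and Isl2 had 35.4 ± 9.46 TPM. The retinoic acid synthesis gene Aldh1a2, which also stands in the meningeal and retinoic acid lists, had 77.2 ± 12.3 TPM. Of the 13 genes 5 also stand in other lists, and levels in whole tissue do not assign these transcripts to motor neurons.

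Among transmitter genes, the glutamate transporter exceeded that of inhibitory transmitters. Slc17a6, the vesicular glutamate transporter gene of the embryonic spinal cord (ENSMUSG00000030500.5, chromosome 7, 51622006 to 51671119), had 21.7 ± 0.841 TPM, against 1.58 ± 0.424 TPM for Slc32a1, the vesicular transporter gene of GABA and glycine (ENSMUSG00000037771.11, chromosome 2, 158610767 to 158615748). Their log2 ratio was 3.81 ± 0.34 (SD, n = 2), or 14-fold, and was 4.05 in replicate 1 and 3.57 in replicate 2, with only 60 and 91 expected counts behind Slc32a1. Of the 5 glutamatergic genes 4 were detected at a list median of 20.0 TPM, with Slc17a7 at 2.10 ± 0.580 TPM and Slc17a8 at 0.125 ± 0.163 TPM. All 8 GABAergic and glycinergic genes were detected at a median of 6.71 TPM, led by the inhibitory fate factor Ptf1a at 10.5 ± 0.474 TPM. The GABA synthesis genes Gad2 and Gad1 had 7.86 ± 0.601 and 7.32 ± 0.233 TPM. Of 10 cholinergic and monoaminergic genes 7 were detected, at a median of 2.72 TPM. The acetylcholine vesicle transporter gene Slc18a3 had 18.96 ± 4.47 TPM, Slc18a2 had 11.98 ± 0.403 TPM, and the catecholamine synthesis genes Th and Ddc had 8.12 ± 1.28 and 5.63 ± 0.502 TPM. Tph2 and Fev, both of serotonin neurons, had 0.170 ± 0.113 and 0.0750 ± 0.106 TPM.

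Hox genes, which encode position along the body axis, were expressed over most of their range, with 36 of 39 detected at a median of 17.4 TPM. Hoxa9 was the highest (ENSMUSG00000038227.11, chromosome 6, 52223100 to 52231089) at 81.0 ± 2.35 TPM, followed by Hoxc6 at 75.4 ± 0.672 TPM, Hoxb2 at 69.6 ± 1.24 TPM and Hoxb6 at 66.5 ± 4.08 TPM. Paralog groups 4 to 10 had a median of 40.9 TPM over 22 genes, groups 1 to 3 had 14.4 TPM over 8 genes, and groups 11 to 13 had 1.65 TPM over 9 genes. The step down came between group 10, at a median of 46.6 TPM, and group 11, at 5.04 TPM, and group 13 reached 0.408 TPM. Hoxb13 and Hoxa13 had 0.265 ± 0.00707 and 0.140 ± 0.0849 TPM. Across the 39 genes, which are not independent replicates, the Spearman rho between paralog number and level was -0.34; it was 0.41 within groups 1 to 10 and -0.87 within groups 9 to 13, ranges chosen after the values were seen.

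**Figure D2:**
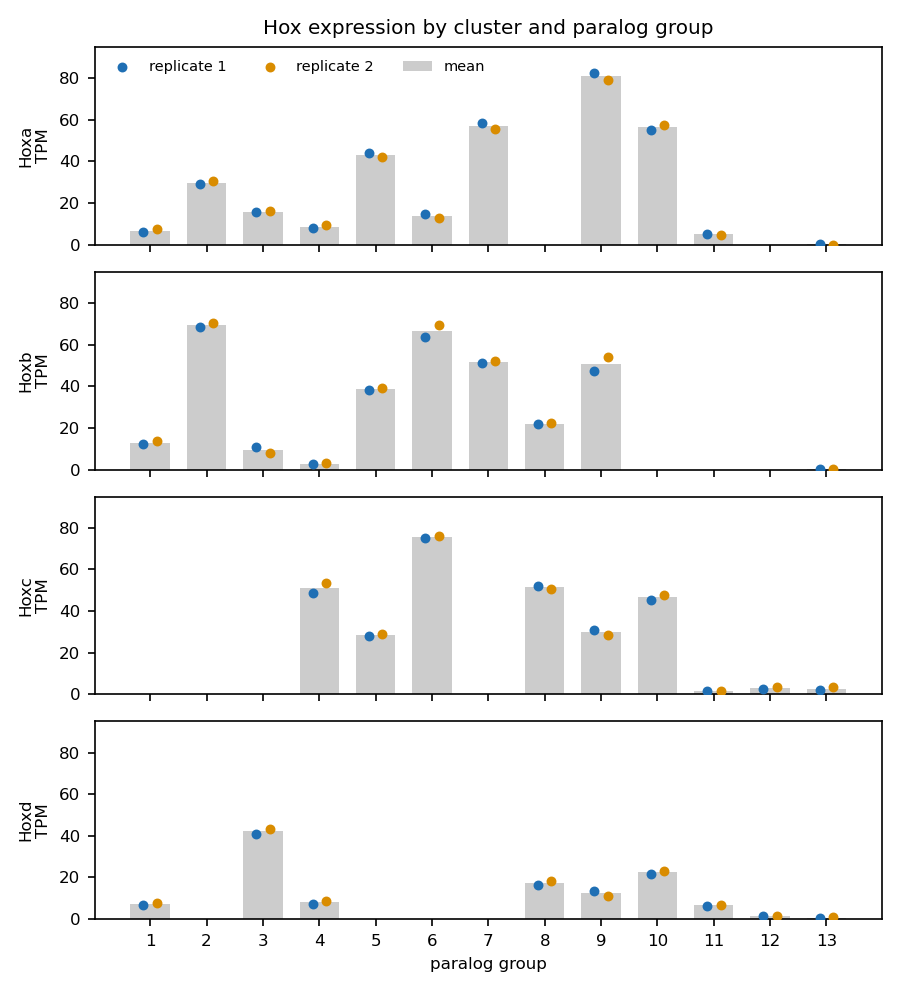
TPM of the 39 Hox genes by paralog group, 1 panel for each of the clusters A to D. Bars are means of the 2 libraries and start at 0, points are the single libraries, and positions with no bar hold no gene of the list or a level close to 0. Levels dropped between paralog groups 10 (median 46.6 TPM) and 11 (5.04 TPM).

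Most genes of rostral brain regions were not detected. Of 18 forebrain and midbrain genes 3 were detected, and the list median was 0.265 TPM, at percentile 3.92 of random lists of protein-coding genes and so inside their central 95%; with posterior mean TPM the median was 0.64. Pax8, a paired-box factor, had the highest level of the list, at 20.3 ± 0.389 TPM. Emx2, Dlx2 and Dlx1, homeobox genes of the forebrain, had 2.20 ± 1.24, 1.73 ± 0.0566 and 1.42 ± 0.686 TPM, and Emx1 had 0.0250 ± 0.0354 TPM. Of 11 hindbrain genes 5 were detected, at a median of 1.18 TPM. Among them were Gbx2 at 35.5 ± 1.41 TPM, Hoxa2 at 29.9 ± 1.09 TPM and Hoxb1 at 12.9 ± 0.976 TPM, whereas Egr2 and Fgf3, markers of early rhombomeres, had 0.685 ± 0.148 and 0.590 ± 0.226 TPM.

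Components of the patterning pathways were broadly expressed. All 11 Sonic hedgehog pathway genes were detected at a median of 8.74 TPM, among them the co-receptor genes Gas1 at 142 ± 11.5 TPM and Boc at 36.3 ± 2.91 TPM, the transducer Smo at 36.8 ± 1.95 TPM and the transcription factor gene Gli3 at 26.3 ± 1.36 TPM. All 13 Wnt genes were detected at a median of 10.4 TPM, with Ctnnb1, encoding beta-catenin, at 531 ± 6.89 TPM, Wnt7b at 61.8 ± 2.57 TPM, the feedback inhibitor Nkd1 at 27.6 ± 0.530 TPM and Lef1 at 20.5 ± 0.219 TPM. Of 13 BMP pathway genes 12 were detected at a median of 5.97 TPM, and the target genes Id3, Id2, Id1 and Id4 stood at 357 ± 12.2, 251 ± 23.9, 96.2 ± 5.70 and 68.6 ± 4.27 TPM. All 13 Notch genes were detected at a median of 36.7 TPM, including the receptor gene Notch1 at 46.1 ± 2.60 TPM. Of 14 retinoic acid genes 12 were detected at a median of 31.2 TPM. The carrier protein genes Crabp1 and Crabp2 had 569 ± 0.658 and 461 ± 29.2 TPM, while the synthesis gene Aldh1a1 had 0.0750 ± 0.106 TPM and the degradation gene Cyp26c1 had 0 counts in both libraries, which allows up to 0.105 TPM in replicate 1 and 0.101 TPM in replicate 2. Of 23 axon guidance genes 22 were detected at a median of 22.0 TPM. The repulsive ligand gene Slit2 had 99.7 ± 14.1 TPM, the commissural receptor gene Robo3 had 69.6 ± 3.37 TPM, the axonal adhesion gene Cntn2 had 43.6 ± 3.90 TPM, Nrp1 had 42.6 ± 5.16 TPM and Unc5d had 0.785 ± 0.120 TPM.

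Transcripts of other tissues were present too. All 13 erythroid genes were detected at a median of 88.8 TPM, and the embryonic globin Hbb-y (ENSMUSG00000052187.3, chromosome 7, 103851749 to 103853216) reached 6724 ± 6.55 TPM. The alpha-type globins Hba-a2, Hba-x and Hba-a1 reached 3669 ± 9.49, 1918 ± 37.1 and 1722 ± 12.5 TPM, with Hba-a1 and Hba-a2 sharing 63.3% and 79.5% of their 100-base windows with another gene. All 18 genes of paraxial mesoderm and connective tissue were detected at a median of 22.7 TPM, led by the collagen genes Col3a1, Col2a1, Col1a2 and Col1a1 at 291 ± 23.1, 170 ± 4.09, 126 ± 6.68 and 93.7 ± 8.31 TPM. All 12 skeletal muscle genes were detected at a median of 33.4 TPM, led by the actin genes Actc1 and Acta1 at 161 ± 17.5 and 72.8 ± 1.61 TPM, the myosin light chain gene Mylpf at 72.2 ± 18.2 TPM and the troponin gene Tnnt1 at 65.2 ± 10.9 TPM. Endothelial genes were detected in 12 of 12 cases at a median of 20.6 TPM, with Egfl7 at 57.1 ± 4.97, Plvap at 39.7 ± 1.44, Cldn5 at 28.7 ± 1.77 and Esam at 27 ± 1.75 TPM. Neural crest and sensory ganglion genes were detected in 14 of 16 cases at a median of 15.4 TPM, including Tfap2b at 36.0 ± 3.15 TPM, whereas Avil and the sodium channel gene Scn10a had 0.530 ± 0.141 and 0.395 ± 0.134 TPM.

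Other non-neural lists were lower or overlapped with the neural ones. All 12 macrophage and microglia genes were detected at a median of 5.46 TPM, with the complement gene C1qb at 20.2 ± 1.41 TPM and the adaptor gene Tyrobp at 13.9 ± 0.382 TPM. All 6 pericyte genes were detected at a median of 5.50 TPM, with Pdgfrb at 18.3 ± 0.990 TPM and Notch3 at 15.2 ± 0.184 TPM. Surface ectoderm genes were detected in 7 of 9 cases at a median of 4.48 TPM, with Perp at 11.8 ± 0.905 TPM and Epcam at 8.22 ± 0.0707 TPM. Notochord genes were detected in 7 of 8 cases at a median of 3.09 TPM, with the keratin genes Krt8 and Krt18 at 11.3 ± 0.163 and 7.30 ± 1.05 TPM and no count for Noto in either library. Meningeal genes were detected in 8 of 9 cases at a median of 50.6 TPM, with Cxcl12 at 79.5 ± 8.09 TPM and Ptgds at 0.25 ± 0.127 TPM, but 5 of the 9 also stand in other lists.

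Of 43346 genes 14299 were detected, of which 12868 were protein-coding, 233 antisense and 214 lincRNA genes; reads of an antisense gene could not be told from those of its partner. Nuclear protein-coding genes took 89.4% ± 0.653 of the expected counts (SD, n = 2), spike-ins 5.37% ± 0.498, lincRNA genes 2.00% ± 0.0922, mitochondrially encoded genes 1.09% ± 0.0495 without their nuclear copies, globins 0.544% ± 0.00661 and replication-dependent histones 0.119% ± 0.00854. Among single genes outside the mitochondrial genome, the tubulin gene Tuba1a stood at 7407 ± 382 TPM, the actin gene Actb at 5591 ± 18 TPM, the ferritin gene Ftl1 at 4236 ± 127 TPM, the translation factor gene Eef1a1 at 3878 ± 11.6 TPM, Ppia at 3850 ± 76.1 TPM, the histone gene Hist1h2ap at 3577 ± 240 TPM and the actin-binding Tmsb4x at 3565 ± 10.0 TPM. The highest entry, Gm42418, stood at 9233 ± 648 TPM, and its neighbour on chromosome 17, Gm26917, at 3282 ± 31.2 TPM. The pair took 1.63% ± 0.0825 of the counts. The annotation types both as lincRNA, and they held most of the share of that class. Whether their reads come from lincRNA was not tested, so the share of that class is to be read with that doubt. Several leading entries shared sequence with other genes. Rn7s1 and Rn7s2 had identical values of 6064 ± 126 TPM with 100% of their windows shared, Gm28437, an unprocessed pseudogene at 5831 ± 338 TPM, was also shared over 100%, in this case with the mitochondrial gene mt-Co3, and Hist1h2ap was shared over 92.2%, Gm42418 over 90.1% and Tuba1a over 65.8%. Gm28437 was given 66545 and 74530 expected counts against 14437 and 9210 for mt-Co3, so its rank outside the mitochondrial genome depends on how these reads were divided. It is 1 of 7 nuclear entries with at least 50% of their windows in a mitochondrial gene, which took 0.407% ± 0.0120 of the counts; with them the mitochondrial share was 1.499% ± 0.0376 (SD, n = 2). Gm22133, a microRNA entry inside Ftl1, had 3927 ± 92.3 TPM from only 672 and 717 expected counts, as its 109 bases lie close to the 99 bases by which lengths were reduced, and it was also shared over 100%.

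Transcript shares within genes were compared to see whether both pools gave the same leading isoform. Of 8016 genes with several annotated transcripts and a mean of 5 TPM or more, 92.7% had the same leading transcript in both libraries (Wilson 95% interval 92.1% to 93.2%). All 36 genes of the splicing and isoform list were detected at a median of 52.4 TPM. The glycolytic enzyme gene Pkm was the highest at 1613 ± 107 TPM, with its leading transcript Pkm-201 at 86.0% ± 0.389 of the gene (SD, n = 2). Cdc42-202 held 86.7% ± 0.679, Tpm3-201 held 89.5% ± 0.481 and Clta-206 held 64.4% ± 0.0990, whereas Tpm1-213 held 34.4% ± 0.70 and Elavl4-211 held 34.3% ± 1.32. The largest moves in the list were Numb-204, which had 55.4% in replicate 1 and 43.6% in replicate 2, Ctnnd1-202 with 22.6% and 34.4%, and Cltb-202 with 53.8% and 64.9%. Of these, Ctnnd1 had different leading transcripts in the 2 libraries.

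The 2 pools matched closely in level. Across 23621 genes with a value above 0, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.992 (bootstrap 95% interval 0.992 to 0.993) and Spearman's rho was 0.964. The common biological coefficient of variation from edgeR was 6.42% over 16201 entries, genes and spike-ins together (jackknife SE 0.00118 as a fraction). Leaving out spike-ins and mitochondrially encoded genes gave 0.0637 as a fraction. Of 17219 genes tested, 740 differed by over 2-fold, 424 higher in replicate 1 and 316 higher in replicate 2, and at a mean of 100 counts or more 14 of 12351 did. Differences were still larger than counting error for many genes. The exact binomial test with Benjamini-Hochberg adjustment at 0.05 separated 3458 genes (20.1%), 1800 higher in replicate 2 and 1658 higher in replicate 1, and chi-square over its degrees of freedom was 5.35, so the files held different libraries. That test compares these 2 libraries only. The spread of the log2 ratio over 65 spike-ins, an SD of 0.27, was 0.879 times that of genes of like count (bootstrap 95% interval 0.613 to 1.11), an interval that includes 1. At 100 counts or more the SD was 0.10 over 46 spike-ins and 0.18 over 12351 genes. These 2 sets were not matched on count, so their SDs may differ through counting error.

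**Figure D3:**
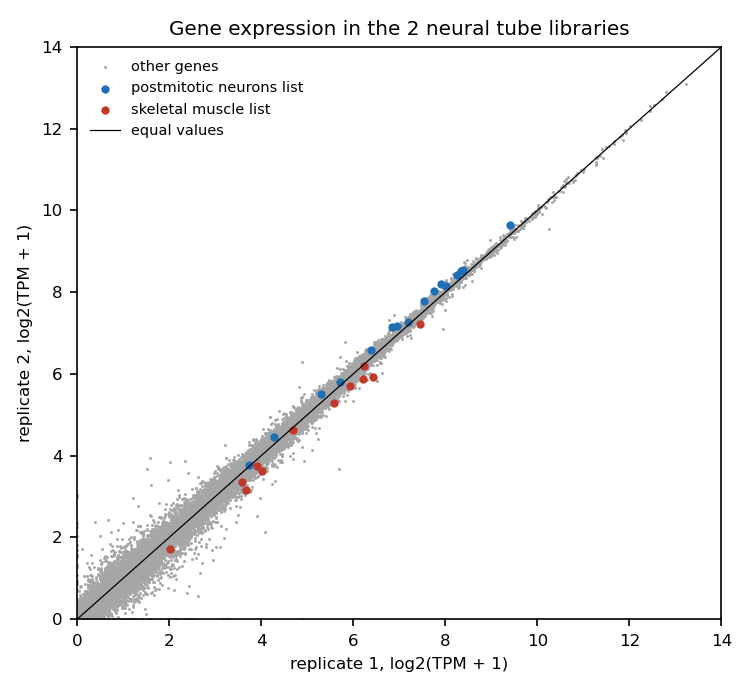
Expression in replicate 1 (horizontal) against replicate 2 (vertical), both as log2(TPM + 1), with 1 point per gene. Blue points are the 16 postmitotic neuron genes, red points the 12 skeletal muscle genes, grey points all others, and the line marks equal values. The points follow the line (r = 0.992), with neuron genes slightly above it and muscle genes slightly below.

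Lists differed between the pools in opposite directions relative to the median of all genes. All 12 skeletal muscle genes were lower in replicate 2, with a median log2 ratio of replicate 2 over replicate 1 of -0.28, and 10 of them passed the exact binomial test. Actc1 had 174 TPM in replicate 1 and 149 TPM in replicate 2 (log2 ratio -0.26, adjusted p = 9.9e-14 by the exact binomial test), and Mylpf and Tnnt1 had log2 ratios of -0.31 and -0.35, whereas Acta1, at -0.09, did not pass. Paraxial mesoderm and connective tissue genes had a median of -0.18, with 15 of 18 lower in replicate 2 and 11 past the test, Col1a1 at -0.24 and Col3a1 at -0.19 among them. BMP genes had a median of -0.23 with 5 of 12 tested genes past the test, all lower in replicate 2, Id2 at -0.24 among them, while Id4, at 0.08, did not pass. Meningeal and imprinted lists were mixed. Meningeal genes had -0.12 with 5 lower and 3 higher in replicate 2, of which 3 and 2 passed the test, Aldh1a2 and Crabp2 being the 2 higher ones. Imprinted genes had -0.08 with 17 lower and 4 higher, of which 9 and 3 passed. Forebrain and midbrain genes had -0.43, with all 8 tested members lower in replicate 2, of which Emx2 alone passed, at -1.39.

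Several lists of neurons and of their formation, but not all, went the other way. All 16 postmitotic neuron genes were higher in replicate 2, with a median log2 ratio of 0.12, and 12 passed the test. Tubb3 had 679 TPM in replicate 1 and 802 TPM in replicate 2 (log2 ratio 0.20, adjusted p = 1.2e-45 by the exact binomial test). Motor neuron genes had the highest median, 0.31, with 12 of 13 higher in replicate 2 and 9 past the test, including Isl2 at 0.48 and Isl1 at 0.20. Neural crest and sensory ganglion genes had 0.24 (15 of 16 higher, 7 past the test), and neurogenesis genes 0.16 (11 of 12 higher, 8 past the test). Notch genes had 0.09 (10 of 13 higher, 5 past the test), but this list alone fell inside the random range when ratios of TPM + 1 were used. Other lists were mixed. Cholinergic and monoaminergic genes had 0.20 with 5 higher and 4 lower, of which 3 and 0 passed the test. Axon guidance genes had 0.07 with 16 higher and 7 lower, of which 7 and 1 passed the test. Splicing and isoform genes had 0.05 with 24 higher and 12 lower, of which 12 and 7 passed. Dorsal and ventral interneuron genes, at 0.06 and -0.01, glutamatergic genes, at -0.03, and GABAergic and glycinergic genes, at 0.09, stayed inside the central 95% of 10000 random lists matched on mean expression. So did progenitor genes, at 0.04, cell cycle genes, at 0.00, erythroid genes, at -0.04, and endothelial genes, at -0.03. In all, 14 of 38 lists lay outside that range, 8 higher in replicate 2 and 6 higher in replicate 1. Ratios are relative to the median of all genes. Scaling by the spike-ins instead moved the median over 12351 genes of 100 counts or more from 0.00 to 0.20. Every list median was then positive except those of skeletal muscle, BMP, and forebrain and midbrain genes, at -0.08, -0.03 and -0.24. Mesoderm, meningeal and imprinted genes turned to 0.02, 0.08 and 0.12, and erythroid and endothelial genes to 0.16 and 0.17. Muscle genes with small ratios, such as Acta1, would turn positive as well. That scaling shifts every gene alike, so it does not test the position of a list among random lists. Each library started from 10 ng of RNA, so spike-in scaling is relative to that input and does not measure RNA per embryo. How evenly the spike-ins were added to the 2 libraries was not tested.

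**Figure D4:**
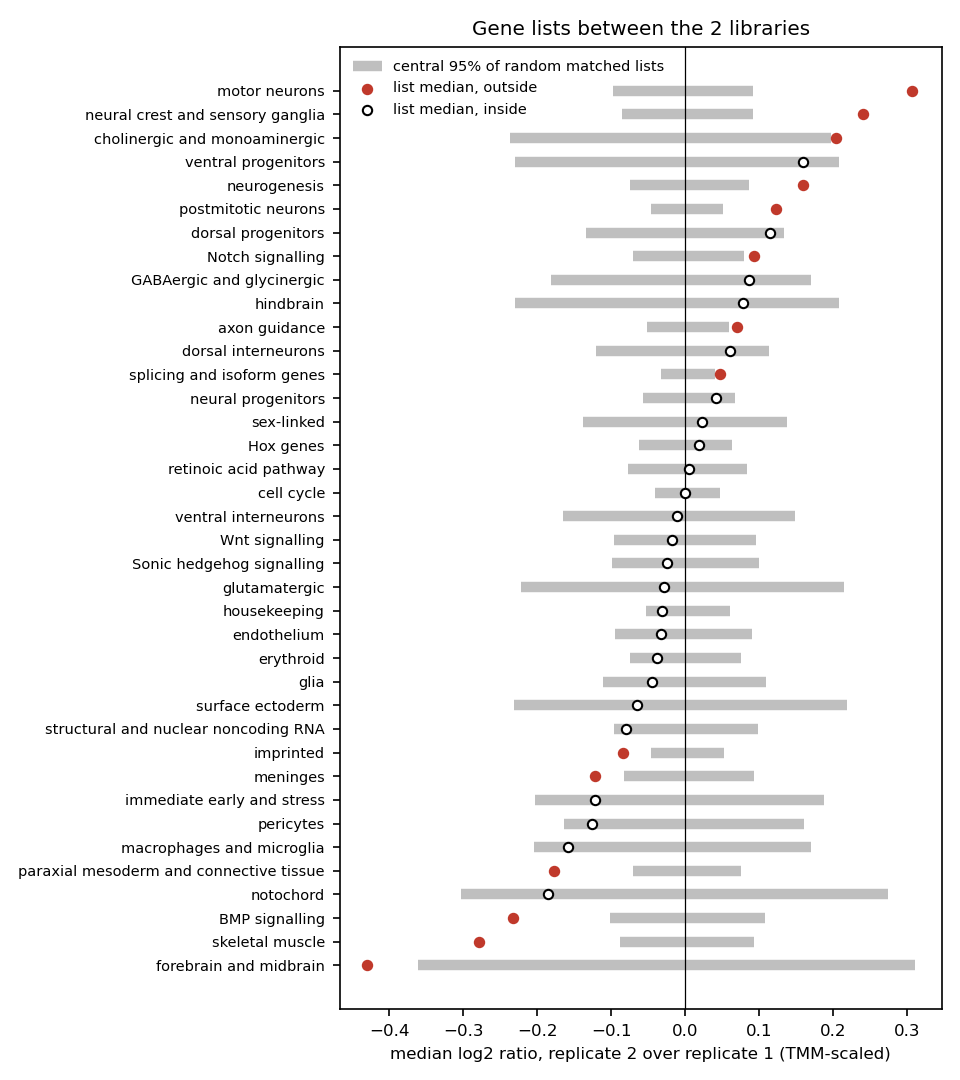
Median log2 ratio of replicate 2 over replicate 1 for each of the 38 lists, scaled by TMM, on the horizontal axis. Grey bars are the central 95% of 10000 random lists matched on mean expression, filled points are the 14 list medians outside it and open points the others. Motor neuron genes (0.31) lay farthest to the right and forebrain and midbrain genes (-0.43, from 8 tested genes) farthest to the left. Under spike-in scaling every median but those of skeletal muscle, BMP, and forebrain and midbrain genes was positive. That scaling is relative to the 10 ng of RNA in each library and does not measure RNA per embryo.

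Apart from entries with no name in the annotation used here, the single genes that differed most at 100 counts or more were of 2 kinds. Some were genes of low level with little sequence shared with other genes. Foxf1, a forkhead factor of visceral mesoderm, had 4.77 TPM in replicate 1 and 2.07 TPM in replicate 2 (log2 ratio -1.23). Pitx1, a hindlimb homeobox gene, had -1.20, the fatty acid receptor gene Cd36 -1.15, Ano4 -1.13, Shroom1 -1.04 and Afp, the alpha-fetoprotein gene of yolk sac and liver, -0.93. In the other direction Scml4 had 1.1, the epithelial splicing regulator gene Esrp2 had 1.01 and Sphkap had 0.95. The others were entries that share most of their sequence with another gene, such as Gm10273 at 2.72, Gm12070 at 1.67, Gm15725 at 1.64, Gm10163 at 1.40, Hist2h2aa1 at 1.08, Gm28557 at 0.97, Gm15501 at 0.91, Gm14434 at -1.05 and Rpl10-ps1 at -0.90. The sum of Hist2h2aa1 and its copy Hist2h2aa2 had a log2 ratio of -0.21, opposite to that of Hist2h2aa1 alone. ENSMUSG00000103057.1 had the lowest ratio, -2.15, and with ENSMUSG00000104300.1, at -0.95, had no name in the annotation used here.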

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

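The 26248 entries named only by a number, which no comparison used, held 8 summed expected counts in replicate 1 and 15 in replicate 2. They are listed because counts were found in entries outside every comparison; no background level was estimated over so many entries. Of the 15 counts in replicate 2, 9 fell on 1 entry of 255 bases. The numbered entries had a median length of 73 bases, below the 99 bases by which lengths were reduced, and the RNA kept was longer than 200 bases. Low counts on entries this short carry little information. What these entries are is not given in the sources used here, so no explanation was tested.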

How the results depend on the processing

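No result below changed direction; the list medians that changed sign under spike-in scaling shifted with the median of all genes. The counts of detected genes (10817 to 18101), of lists with at least 50% of members detected (30 to 37), of lists outside the random range (13 to 14, the Notch list being lost with TPM + 1) and of genes past the binomial test (3202 to 3465) stayed within 1.5 times their main values under every alternative run. For lists outside the random range, spike-in scaling is no test, since it shifts lists and random lists alike. The replicate correlation was 0.972 with a pseudocount of 0.1, 0.988 at a mean TPM of 1 or more and 0.996 with posterior mean TPM. The common coefficient of variation was 0.0672 without a filter, 0.0592 at 100 counts in both libraries and 1e-04 as the median DESeq2 gene-wise value, where at least 50% of genes sit at the lowest value that DESeq2 allows. Genes over 2-fold apart numbered 2195 without a filter, 34 at 100 counts in 1 library and 94 by TPM with a pseudocount of 1. Dropping the filter admits more low-count genes, while the stricter filter removes them and the pseudocount shrinks their ratios. The spike-in ratio was 0.569 for the 46 spike-ins of 100 counts or more against all genes of 100 counts or more, not matched on count. For dorsal minus ventral progenitors the log2 difference was 1.27 with pseudocount 0.1, 1.02 with posterior mean TPM, 1.21 with library-scaled counts, and 1.12 to 1.16 with a replicate left out; for interneurons it was 0.85, 0.80 and 0.54. With library-scaled counts, which ignore gene length, the progenitor minus neuron difference was -1.44, the Slc17a6 to Slc32a1 ratio 4.45 and the Hox rho -0.35; with a replicate left out the Hox rho was -0.338 to -0.331. As shares of TPM, spike-ins took 12.5%, mitochondrial genes 2.38%, globins 1.63%, histones 0.471%, protein-coding genes 76.6% and lincRNA genes 1.83%, since TPM weights short transcripts more. The same leading transcript was found in 89.8% of genes at 1 TPM, 94.4% at 20 TPM and 98.8% where it held 60% or more. Among single named genes and list medians, 742 values stayed within their replicate spread and 456 moved beyond it, mostly on a change of unit, which rescales every gene. For the other moves the cause was not tested. No paired analysis was possible because the series holds 1 group. With 2 libraries an SD has 1 degree of freedom, and genes under about 10 counts were not resolved between the pools.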

Other observations

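The tests of tissue makeup below were chosen after the list results were seen; those of length and GC content, shared sequence and counting noise were written before their results.

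Imprinted genes, expressed from 1 parental copy and many of them growth regulators, were abundant, with 20 of 21 detected at a median of 116 TPM. Mest stood at 1265 ± 73.4 TPM, Nnat at 1123 ± 68.3 TPM, the cell cycle inhibitor gene Cdkn1c at 746 ± 26.2 TPM and the noncoding Meg3 at 399 ± 0.417 TPM, while Rtl1 had 0.825 ± 0.00707 TPM (SD, n = 2). All 12 housekeeping genes were detected at a median of 831 TPM, with Gapdh at 1853 ± 12.5 TPM. Of 10 structural and nuclear noncoding RNAs 8 were detected at a median of 31.3 TPM, among them Malat1 at 2341 ± 203 TPM and Rn7sk at 214 ± 0.778 TPM, whereas Neat1, the scaffold RNA of paraspeckles, had 0.495 ± 0.163 TPM and the telomerase RNA gene Terc 0.435 ± 0.12 TPM.

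Of 12 immediate early and stress genes 8 were detected at a median of 2.42 TPM, at percentile 31.6 of random lists of protein-coding genes. Ier2 and Jun stood at 59.3 ± 3.59 and 40.2 ± 1.31 TPM, the heat shock gene Hspb1 at 23.4 ± 0.884 TPM and Ddit3 at 17.3 TPM in both libraries, while Fosl2 had 0.565 ± 0.191 TPM and Fosb had no count. Of 8 sex-linked genes 6 were detected at a median of 9.73 TPM. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d had 19.2 ± 0.297, 13.7 ± 1.95 and 11.4 ± 1.85 TPM beside 17.9 ± 0.742 TPM for Xist, the RNA that silences an X chromosome in females, in pools that the labels give as male and female together. Sry and Zfy1 had no count.

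Relative to the median of all genes, postmitotic neuron genes were higher in replicate 2 and muscle genes higher in replicate 1, by a log2 difference between the list medians of 0.40 (bootstrap 95% interval 0.36 to 0.49); 0 of 12 muscle genes and 8 of 16 neuron genes also stand in another list. Removing a trend on gene length and GC content left 102% of it, which argues against that bias as the whole cause. An equally lower share of every non-neural tissue in replicate 2 would lower blood and vessel genes as much as muscle genes. Instead, erythroid and endothelial genes stood above muscle genes by 0.24 (0.20 to 0.32). Pericyte, macrophage, notochord and surface ectoderm medians, at -0.13, -0.16, -0.19 and -0.06, lay between the muscle and endothelial medians and inside their random ranges. Neural crest and sensory ganglion genes were higher in replicate 2. The values thus argue only against an equal fall, and an unequal fall in non-neural tissue is left open. A larger neural share in replicate 2 alone cannot be told apart from a larger share of neurons, since neuron genes exceeded progenitor genes by 0.0818 with an interval of -0.01 to 0.20. Different amounts of adjoining somite tissue, or a small difference in stage, between the pools may contribute and were not tested, since the labels give both pools the same age and tissue.

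The 14 genes over 2-fold apart at a mean of 100 counts or more were beyond counting error, since 100 Poisson draws at the same means gave at most 0 such genes. Of the 13 with a sequence in the annotation used here, 6 had 50% or more of their windows in another gene, against 0 to 2 in random gene sets of that size and 3.61% of all genes, so a split of reads among near-identical copies may account for part of them. The other 7, with less shared sequence, remain open, and no biological explanation was tested for them.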
